A study of Mus musculus with 15 samples.

How the data were processed

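The series holds 15 arrays of total RNA from mouse interscapular brown adipose tissue, 5 per group, each from its own animal: controls (replicates 31 to 35), FGF21 (36 to 40) and the aFGFR1/KLB antibody (41 to 45). Groups were taken from the sample titles. Replicate numbers do not repeat between groups, so no samples were paired. The labels describe a biotin label by a commercial service and give no scan date or batch.

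The deposited table gives 1 normalised intensity per probe set and array on a linear scale (5.58 to 34652). Per the submitters' processing notes the authors used RMA, a background correction, quantile normalisation and probe set summary; no version, chip definition or later step is stated, and the scanner images were not used here. The medians of the 15 arrays lay between 50.6 and 52.1, the lower quartiles between 17.5 and 19.07 and the upper quartiles between 189.1 and 215.6. FGF21 36 (17.5 and 215.6) and control 34 (17.95 and 208.9) had the lowest lower and the highest upper quartiles. Values were taken to log2, with no further normalisation. Arrays give no read depth; their number limits the precision.

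Of 45101 probe sets, 34958 carried 1 gene symbol in GEO's platform annotation, 932 carried several and 9211 were not listed and are unnamed here. Of the 34958, 34754 matched a RefSeq entry (GRCm38.p6, used for names alone) through their Entrez ID, and 0 symbols differed. Each of the 18194 genes was represented by the probe set with the highest mean over all samples, and the 13174 genes above the 40th percentile of probe set means (5.06 on the log2 scale) were tested, which left out 5020. For 11 named genes called on the probe set used, at least 1 other probe set above the filter did not pass in the same comparison (adjusted over all probe sets): Ak4, Akap1, Arhgap26, Cyp2b10, Dio2, Fam20c, Fdft1, Lmna, Sdc4, Spry4 and Tnfrsf12a.

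A one-way model with the 3 groups was fitted to all 15 samples (12 residual degrees of freedom) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p was adjusted by Benjamini and Hochberg within each of the 3 comparisons, with a threshold of 0.05. Adjusted p in all texts are limma's unless camera is named. Genes named were those with the 10 largest rises and falls in each comparison with control, or 8 between the treatments, among genes that passed with no overlap between groups; up to 4 members per list with the smallest p; and Ucp1, Fgf21, Fgfr1, Klb, Adipoq, Dusp6, Spry4, Ppargc1a and Dio2 in every comparison. Sdc4 and the 6 genes of similar size in both treatments, in the comparison of the treatments, Car14 and Thbs1 in that of the antibody with control, and the macrophage genes Gpnmb, Lyz2 and C1qb were named after their values were seen. Predicted genes with clone-like symbols were counted and not named. Slc2a5, Hmga2-ps1, Lmna, Nav3, Insig1, Arhgap26, Nim1k and Akap1 also met the rule and were called, with log2 fold changes of −0.99 and −1.07 (antibody against control) and of −0.93, −0.91, 0.82, 0.61, 0.58 and 0.52 (antibody against FGF21); the calls of all but Hmga2-ps1 ended in at least 5 of the 15 fits without 1 sample.

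37 gene lists (774 distinct genes, 645 tested) covering pathways of brown fat and FGF signalling and markers of cell types that the tissue piece could hold were written down with the design, the tests, the naming rule and most alternatives before the data were examined. 36 had at least 4 tested members. Each was tested with camera (preset correlation 0.01, adjusted over the 36 lists), which compares it with all other genes; with camera and an estimated correlation; with fry, which asks whether members move one way on balance; and with an exact two-sided permutation of the list mean over the 252 splits of 5 against 5 samples (smallest possible p 0.00794). Against control, 15 lists passed in camera with the antibody and 9 with FGF21, and 13 passed between the treatments. With an estimated correlation 0, 1 and 0 passed (3, 3 and 1 at an unadjusted p under 0.05), in fry 3, 4 and 1, and in the exact permutation test 0 after adjustment (10, 4 and 8 at an unadjusted p under 0.05).

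Agreement between the treatments was measured across genes. It was set beside 1000 simulations of unchanged groups, 20 divisions of the controls between both comparisons, and the overlap of independent lists. That overlap was also counted with divided controls, a count chosen after the results were seen. Each simulation drew its groups from the residuals of all 15 samples and compared both treated groups with the same simulated control group. The fit was tested on simulated data made from these arrays' means and spread, with 200 of 13174 genes changed in each of 5 runs: for the antibody against control it recovered 66.9%, 89.6% and 97.6% of changes of 0.5, 1 and 2 on the log2 scale with 3.86% false calls, and for FGF21 against control 66.0%, 91.0% and 98.2% with 4.39%. The simulated noise was independent between genes, unlike these arrays, whose first principal component held 40.8% of the variance. The simulated shares of false calls therefore need not hold for the real data. Alternatives changed the filter, the probe set rule, the normalisation, the spread estimate, array weights, the samples fitted, a muscle covariate and the thresholds, and left out each sample in turn. 3 alternatives, without control 34 and FGF21 36 and with macrophage covariates, were chosen after seeing the data. No samples were left out of the reported fit, and probe sets with several symbols or none were tested apart.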

Results

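Transcripts were measured in the brown fat between the shoulder blades, a depot specialised for heat production, from 15 adult male C57BL/6N mice kept on a high-fat diet. 5 mice were controls, for which the labels name no injected substance. Another 5 received FGF21, a hormone that signals through the receptor FGFR1 and its co-receptor KLB, in 2 daily doses of 1 mg/kg each. The last 5 received bFKB1, an antibody that activates the FGFR1/KLB complex (aFGFR1/KLB below), as a lone dose of 10 mg/kg. All tissue came from day 5. Each sample was read on its own array. Median intensities lay between 50.6 and 52.1, and samples correlated with each other at 0.925 to 0.996 across genes. The number of arrays limits the precision, and the median standard error of a fold change was 0.10 on the log2 scale.

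The comparison of antibody-treated with control mice asks which transcripts of brown fat respond to activation of FGFR1/KLB by the antibody. The largest rises were those of Sgk2, a kinase related to the glucocorticoid-regulated kinase Sgk1, by 2.84 ± 0.32 (log2 fold change ± SE, n = 5 per group, adjusted p = 0.000401) and of Mfsd2a, a lysophospholipid transporter, by 2.81 ± 0.38 (adjusted p = 0.00117). Elovl3, an elongase of long-chain fatty acids typical of active brown fat, rose by 2.10 ± 0.23, from a control mean of 10.25 to 12.35 (adjusted p = 0.000331). Pla2g2e, a secreted phospholipase, rose by 1.72 ± 0.12 (adjusted p = 3.8e-06). The mitochondrial carrier Slc25a34 rose by 1.71 ± 0.20. Further large rises were those of Itih4 (1.71), Ffar4, a receptor for long-chain fatty acids (1.54), and Ehhadh, an enzyme of peroxisomal fatty acid oxidation (1.49). Ak4, a mitochondrial adenylate kinase, rose by 1.70 on its brightest probe set. Of its other probe sets above the filter, 1 rose by 1.18 and 2 did not pass. The largest falls among genes with a single-symbol probe set were those of Sorcs2, a sorting receptor (−1.66 ± 0.24), Col12a1, a collagen (−1.64 ± 0.31), Fam20c, a kinase of the secretory pathway (−1.32 ± 0.23), Mcam (−1.28 ± 0.19) and the receptor kinase Kit (−1.14 ± 0.15). Fdft1, squalene synthase, was lower by −1.33 ± 0.16, although 2 of its other probe sets did not pass. Cyp2b10, a cytochrome P450, was higher by 1.92 ± 0.43 (adjusted p = 0.0202), but its adjusted p was 0.0556 without aFGFR1/KLB 41, 0.0515 without aFGFR1/KLB 43 and 0.0507 without control 33.

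In all, 682 of 13174 genes changed with the antibody (limma, Benjamini-Hochberg adjusted p under 0.05), 354 up and 328 down. Of these, 214 changed by at least 1.5-fold, 131 up and 83 down. The 5 treated and 5 control values did not overlap for 568 of the 682 genes and for 8.61% of all genes, where chance alone gives 0.794%. Leaving out a single array moved the count to 454 (control 31), 365 (control 32), 408 (control 33), 1140 (control 34), 386 (aFGFR1/KLB 41), 336 (aFGFR1/KLB 42), 421 (aFGFR1/KLB 43) or 372 (aFGFR1/KLB 44). Without control 34 the balance turned to mostly lower, with 483 up and 657 down. Without control 34 and FGF21 36 together, 713 were up and 918 down. With arrays centred on ribosomal protein genes, which moved the median of all genes by 0.13, the count was 134, of which 85.1% were higher, against 51.9% without that centring.

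Among the gene lists fixed beforehand, the antibody raised the FGF and ERK feedback and target genes (5 of 19 members up, 0 down, 7 adjusted over the list alone; mean 0.28, camera adjusted p = 0.000904, adjusted p = 0.517 with an estimated correlation). The members with the smallest p were Dusp4 (1.25 ± 0.13) and Dusp6 (1.10 ± 0.14), phosphatases that switch off MAP kinases, and Spry4 (0.88 ± 0.12) and Spred2 (0.80), inhibitors of the Ras to ERK cascade. Averaging all probe sets of Spry4 ended its call. Heat shock genes rose as a group (4 of 14 up, 0 down; adjusted over the list alone 7 up and 1 down; mean 0.26, camera adjusted p = 0.000145, adjusted p = 0.401 with an estimated correlation), with Bag3, a co-chaperone, among them (0.41, adjusted p = 0.0147). De novo lipogenesis genes fell as a group, 2 of 21 singly and 9 adjusted over the list alone (mean −0.24, camera adjusted p = 0.000904, adjusted p = 0.693 with an estimated correlation). Endothelial markers rose (1 of 18 up, 2 adjusted over the list alone; mean 0.15, camera adjusted p = 0.00738, adjusted p = 0.790 with an estimated correlation), led by the transcription factor Sox17 (0.63, adjusted p = 0.0055).

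Thermogenic and brown adipocyte genes also rose as a list, with 6 of 28 members up and 2 down, and 8 up and 2 down adjusted over the list alone (mean 0.22, camera adjusted p = 0.00584, adjusted p = 0.790 with an estimated correlation). Dio2, the deiodinase that activates thyroid hormone in brown fat, rose by 1.16 ± 0.24 (adjusted p = 0.0142), and Ntrk3, a neurotrophin receptor, fell by 1.02 ± 0.22. Of the other 2 probe sets of Dio2, 1 was higher by 0.93 (adjusted p = 0.0498 over all probe sets) and 1 did not pass (0.82, adjusted p = 0.12). Ucp1, the uncoupling protein of brown fat mitochondria, was higher by 0.19 ± 0.05 (adjusted p = 0.0494), with all 5 treated values above all 5 control values. Ppargc1a, a regulator of mitochondrial genes, was higher by 0.60 ± 0.17 (adjusted p = 0.0486). Ucp1 was the gene with rank 8 of 13174 in mean intensity, at 14.69, where the brightest gene was at 15.02. The call of Ucp1 held only when FGF21 36 was the array left out, with adjusted p up to 0.119 without another array. That of Ppargc1a held only when control 34, FGF21 36, FGF21 39 or aFGFR1/KLB 45 was left out, with adjusted p up to 0.117 otherwise. Its other probe sets above the filter were higher by 0.50 to 0.70 (adjusted p 0.0224 to 0.0431 over all probe sets, where the one used had 0.0501).

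Fatty acid oxidation genes rose as a list (2 of 23 up; mean 0.17, camera adjusted p = 0.00372, adjusted p = 0.790 with an estimated correlation). So did glucose uptake and glycolysis (3 of 20 up, 7 adjusted over the list alone; mean 0.11, camera adjusted p = 0.00584, adjusted p = 0.693 with an estimated correlation). Branched-chain amino acid catabolism rose (2 of 21 up, 5 adjusted over the list alone; mean 0.15, camera adjusted p = 0.00738, adjusted p = 0.846 with an estimated correlation). Pfkp, the platelet form of phosphofructokinase, rose by 0.68 and Dbt, a subunit of the branched-chain ketoacid dehydrogenase, by 0.58. Circadian clock genes rose (5 of 18 up, 7 up and 1 down adjusted over the list alone; mean 0.23, camera adjusted p = 0.0082, adjusted p = 0.521 with an estimated correlation), among them Per1 (1.05), Ciart (0.87), Per2 (0.73) and Nfil3 (0.65). ATF4 and integrated stress response genes were higher by camera (1 of 18 up, Trib3 by 0.81; list mean 0.18, camera adjusted p = 0.0265, adjusted p = 0.520 with an estimated correlation). Lipolysis, lipid droplet and lipid uptake genes were higher too (3 of 21 up and 1 down, 5 up and 2 down adjusted over the list alone; mean 0.06, camera adjusted p = 0.0281, adjusted p = 0.693 with an estimated correlation). Abhd5, the activator of the lipase ATGL, rose by 0.78 (adjusted p = 0.00233). Control 34 had macrophage and collagen transcripts far above those of the other controls. Without it, none of these lists passed and neither did the thermogenic list. Camera's adjusted p was then 0.0735 for fatty acid oxidation, 0.068 for glycolysis and 0.277 for branched-chain amino acids. It was 0.138 for the clock, 0.0664 for ATF4, 0.198 for lipolysis and 0.0801 for thermogenic genes. The lipolysis list also missed the threshold without aFGFR1/KLB 41 (adjusted p = 0.054). Without control 34 and FGF21 36 together, fatty acid oxidation passed (0.12, adjusted p = 0.043, but 0.754 in camera with an estimated correlation) and the other 6 did not.

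The lists that fell with the antibody other than lipogenesis were markers of other cell types and matrix. Collagens and extracellular matrix averaged −0.41 (1 of 25 down; camera adjusted p = 0.0372, adjusted p = 0.956 with an estimated correlation). Fibroblast and adipose progenitor markers averaged −0.43 (0 of 12 down by limma, 1 at an unadjusted p under 0.05; camera adjusted p = 0.0218, adjusted p = 0.790 with an estimated correlation). Without control 34 these means were −0.07 (adjusted p = 0.823) and −0.16 (adjusted p = 0.501). Both lists also missed the threshold without aFGFR1/KLB 42 (each adjusted p = 0.0909), as did collagens without aFGFR1/KLB 44 (adjusted p = 0.0698). Schwann cell and nerve markers averaged −0.15 (0 of 9 down by limma, 3 at an unadjusted p under 0.05; camera adjusted p = 0.0372, adjusted p = 0.693 with an estimated correlation). That call ended without control 31, control 33, aFGFR1/KLB 42 or aFGFR1/KLB 44, with adjusted p of 0.058, 0.147, 0.0713 and 0.0537. It held without control 34 and FGF21 36 together (−0.20, adjusted p = 0.00951), but not in camera with an estimated correlation (adjusted p = 0.348). B and plasma cell markers averaged −0.30 (0 of 6 down by limma, 3 adjusted over the list alone and 3 at an unadjusted p under 0.05; camera adjusted p = 0.0413, adjusted p = 0.517 with an estimated correlation). Their call ended without control 31, 33, 34 or 35 or without aFGFR1/KLB 42, 43 or 45, with adjusted p between 0.0501 and 0.0713.

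The comparison of FGF21-treated with control mice asks the same of the natural ligand. Among genes with a single-symbol probe set, Thbs1, which encodes the matrix protein thrombospondin, rose most, by 2.80 ± 0.23 (log2 fold change ± SE, n = 5 per group, adjusted p = 1.1e-05), from a control mean of 5.32 to 8.13. Sgk2 rose by 2.42 ± 0.32, the MAP kinase phosphatase Dusp4 by 2.21 ± 0.13 (adjusted p = 3.8e-07), the metallothionein Mt2 by 2.03 ± 0.17, and Sdc4, a syndecan of the cell surface, by 1.95 ± 0.10 (adjusted p = 9.5e-08). Dio2 rose by 1.89 ± 0.24 (adjusted p = 0.000594), Pla2g2e by 1.80 ± 0.12, Depp1 by 1.79 ± 0.29, Prg4 by 1.76 ± 0.34 and Cyp4b1 by 1.70 ± 0.16. The largest falls were those of Rasl12, a Ras-like protein (−1.76 ± 0.15, adjusted p = 1.1e-05), Fam20c (−1.63 ± 0.23), Kit (−1.27 ± 0.15), Rasd1 (−1.24 ± 0.20) and Trarg1, a regulator of glucose transporter traffic (−1.22 ± 0.17). Ntrk3 (−1.21), Pnpla3, a lipid droplet protein (−1.09), Rnf182 (−1.09), Mcam (−1.07) and Dixdc1 (−0.93) fell as well.

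With FGF21, 833 of 13174 genes changed (limma, adjusted p under 0.05), 348 up and 485 down. Of these, 237 changed by at least 1.5-fold, 128 up and 109 down. The values of both groups did not overlap for 518 of the 833 genes and for 5.25% of all genes, where chance gives 0.794%. Leaving out a single array moved the count to 555 (control 31), 463 (control 32), 513 (control 33), 2097 (control 34) or 526 (FGF21 39). With arrays centred on ribosomal protein genes the count was 137, of which 71.5% were higher, against 41.8% without that centring, and with only these 10 arrays fitted it was 322.

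FGF and ERK feedback and target genes rose with FGF21 by 0.64 on average, 7 of 19 singly and 9 adjusted over the list alone (camera adjusted p = 6.5e-12, adjusted p = 0.0456 with an estimated correlation). Dusp6 rose by 1.48 ± 0.14, Spry4 by 1.48 ± 0.12 and Spred2 by 1.06. De novo lipogenesis genes fell by 0.33 on average, 6 of 21 singly and 11 adjusted over the list alone (camera adjusted p = 8.2e-05, adjusted p = 0.823 with an estimated correlation). Members that fell included Pnpla3 (−1.09), the transcription factor Srebf1 (−0.56), which drives lipogenic genes, and Mid1ip1, an activator of acetyl-CoA carboxylase (−0.49). Heat shock genes rose (4 of 14 up, 5 adjusted over the list alone; mean 0.26, camera adjusted p = 0.000141, adjusted p = 0.264 with an estimated correlation), with Bag3 up by 0.56. Endothelial markers rose by 0.20 on average (2 of 18 up; camera adjusted p = 0.000399, adjusted p = 0.823 with an estimated correlation), with the TGF-beta co-receptor Eng up by 0.40. Immediate early genes were higher as a list (0 of 14 by limma, 5 at an unadjusted p under 0.05, 2 up and 1 down adjusted over the list alone; mean 0.30, camera adjusted p = 0.00848, adjusted p = 0.560 with an estimated correlation).

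Macrophage markers averaged 0.69 higher with FGF21, although 0 of 22 passed singly in limma and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.0017, adjusted p = 0.869 with an estimated correlation). Collagens and extracellular matrix averaged 0.40 higher (2 of 25 up, 3 adjusted over the list alone; camera adjusted p = 0.0017, adjusted p = 0.869 with an estimated correlation). With the macrophage mean of each sample as a covariate their mean was −0.05. FGF21 36 carried high levels of both lists and of muscle markers, and without it the macrophage mean was 0.36 (adjusted p = 0.185) and the collagen mean 0.17 (adjusted p = 0.197). With control 34 left out as well, both lists passed, at 0.80 (adjusted p = 0.000162, 1 of 22 up) and 0.51 (adjusted p = 2.7e-05, 5 of 25 up). In camera with an estimated correlation neither passed in that fit (adjusted p = 0.732 and 0.6445). The macrophage list also missed the threshold without control 32 (adjusted p = 0.0503). Oxidative phosphorylation genes averaged −0.07 (0 of 69 down by limma, 6 at an unadjusted p under 0.05; camera adjusted p = 0.00848, adjusted p = 0.954 with an estimated correlation). The call ended without FGF21 36 (adjusted p = 0.559) or control 32 (adjusted p = 0.0641). Cholesterol synthesis genes averaged −0.20 (2 of 20 down, 4 adjusted over the list alone; camera adjusted p = 0.0326, adjusted p = 0.869 with an estimated correlation). Dhcr7, the last enzyme of that pathway, fell by 0.67 (adjusted p = 0.00213), while the list missed the threshold without control 31, control 32, control 33, FGF21 36 or FGF21 39, with adjusted p of 0.07, 0.0804, 0.0696, 0.13 and 0.199. Without control 34 and FGF21 36 together it passed (−0.24, adjusted p = 0.00995, 7 of 20 down), but not in camera with an estimated correlation (adjusted p = 0.749).

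The thermogenic list did not pass with FGF21 (3 of 28 up and 3 down; 5 up and 3 down adjusted over the list alone; mean 0.12, median −0.00, camera adjusted p = 0.519), and its members moved apart. Without FGF21 36 it passed (mean 0.21, adjusted p = 0.0426), but not without control 34 and FGF21 36 together (mean 0.15, adjusted p = 0.421). It also passed with a macrophage covariate (0.23, adjusted p = 0.00768) and with macrophage and muscle covariates (0.20, adjusted p = 0.018). Dio2, Elovl3 (1.60) and Bmp8b, a secreted factor of brown fat (1.33), rose, and Prdm16, a regulator of brown fat identity (−0.87), and Ntrk3 fell. Ucp1 was 0.10 ± 0.05 above control with FGF21 (adjusted p = 0.290) and Ppargc1a 0.57 ± 0.17 (adjusted p = 0.0559). Ppargc1a passed without control 34 (adjusted p = 0.0435) or FGF21 36 (0.71, adjusted p = 0.00695).

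**Figure D1:**
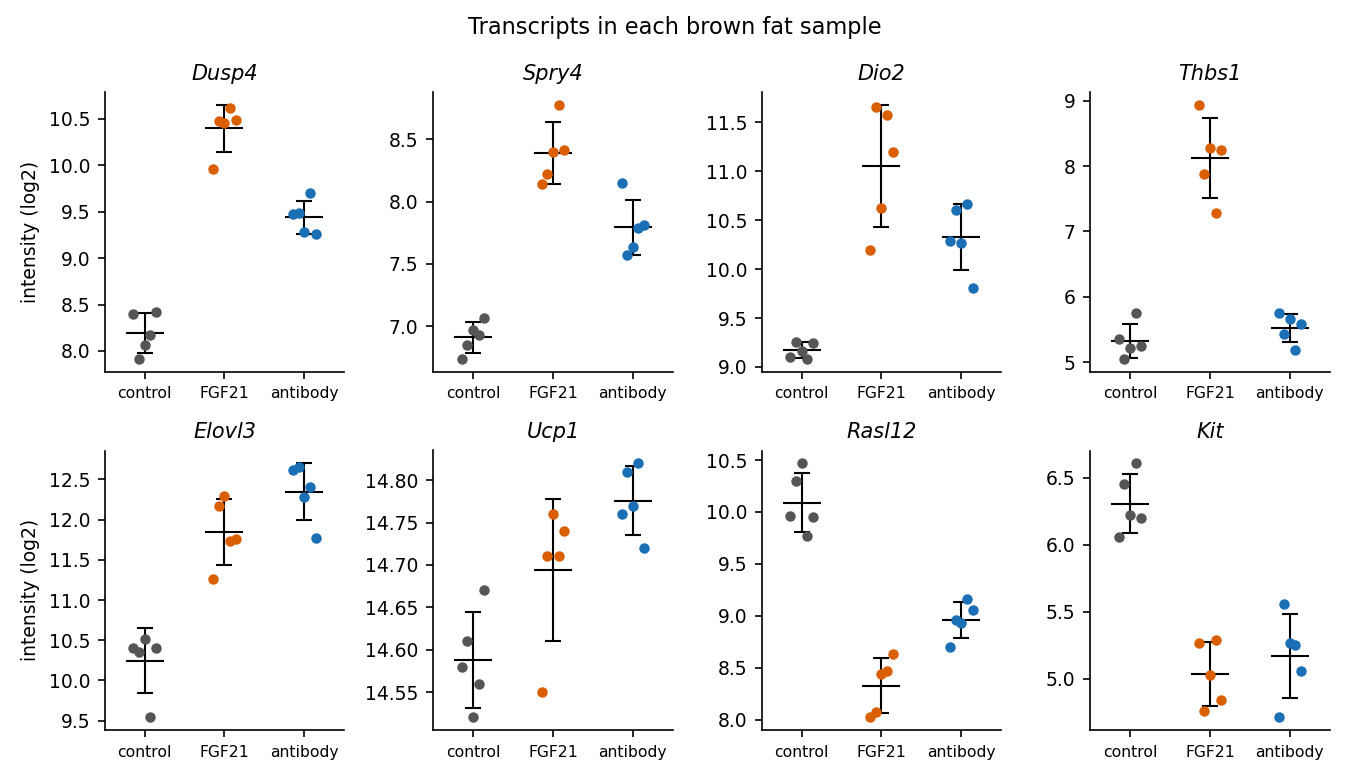
Log2 intensity of 8 genes in each of the 15 samples, with the mean and SD of each group of 5; the scale differs between panels. Dusp4, Spry4 and Thbs1 were highest with FGF21, Elovl3 and Ucp1 had their highest mean with the antibody, and Rasl12 and Kit were lower with both treatments than in any control.

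The comparison of the antibody with FGF21 asks where both ways of activating the receptor complex differ, at doses and schedules that were not matched. Thbs1 was lower with the antibody by −2.61 ± 0.23 (n = 5 per group, adjusted p = 0.000215), at 5.52 against 8.13, and its antibody level was close to that of control (0.20 ± 0.23, adjusted p = 0.711). Crip2 (−1.34 ± 0.18, adjusted p = 0.00646), the calcium-binding protein S100g (−1.01 ± 0.14, adjusted p = 0.0089) and Dusp4 (−0.96 ± 0.13, adjusted p = 0.0068) were also lower with the antibody. Tnfrsf12a, the receptor of the cytokine TWEAK, was lower by −1.55 ± 0.24 (adjusted p = 0.0121; 0.0506 without FGF21 40). Net1, an activator of RhoA, was lower by −1.22 ± 0.19 (adjusted p = 0.0121; 0.0506 without FGF21 40 and 0.0509 without aFGFR1/KLB 42). Car14, a membrane-bound carbonic anhydrase, was higher with the antibody than with FGF21 by 1.45 ± 0.15 (adjusted p = 0.000614) and higher than in controls by 1.22 (adjusted p = 0.000735). Wscd2 (0.87 ± 0.11, adjusted p = 0.00304), Ttc28 (0.81 ± 0.12, adjusted p = 0.0099) and the acyl-CoA synthetase Acsl3 (0.58 ± 0.08, adjusted p = 0.0068) were also higher with the antibody. Sdc4 was lower by −0.53 ± 0.10 (adjusted p = 0.04), although its other probe set did not pass (−0.34, adjusted p = 0.164). Among genes that did not pass here, the differences were −0.60 for Spry4 (adjusted p = 0.0522), −0.38 for Dusp6 (adjusted p = 0.278), −0.73 for Dio2 (adjusted p = 0.220), 0.04 for Ppargc1a (adjusted p = 0.939) and 0.09 for Ucp1 (adjusted p = 0.474). Spry4 passed without control 34 (adjusted p = 0.0297), FGF21 36 (adjusted p = 0.0423) or aFGFR1/KLB 41 (adjusted p = 0.0367). Without control 34 and FGF21 36 together, Spry4 (−0.66, adjusted p = 0.022) and Dio2 (−0.94, adjusted p = 0.0342) passed.

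In all, 49 of 13174 genes differed between the treatments (limma, adjusted p under 0.05), 17 higher and 32 lower with the antibody. The difference was at least 1.5-fold for 18, 5 higher and 13 lower. Both groups did not overlap for 48 of these genes and for 4.69% of all genes, where chance gives 0.794%. The count was 26 without control 31, 30 without control 32, 251 without control 34, 30 without control 35, 28 without FGF21 39, 10 without FGF21 40, 19 without aFGFR1/KLB 41, 11 without aFGFR1/KLB 42, 21 without aFGFR1/KLB 43, 17 without aFGFR1/KLB 44 and 28 without aFGFR1/KLB 45. It was 241 without control 34 and FGF21 36, with all 49 genes still called, and 8 with arrays centred on ribosomal protein genes. With array weights it was 832, 470 higher and 362 lower with the antibody, so the balance of directions turned.

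FGF and ERK feedback and target genes were lower with the antibody than with FGF21, by −0.36 on average, with 1 of 19 down singly and 8 adjusted over the list alone (camera adjusted p = 4e-07, adjusted p = 0.287 with an estimated correlation). 16 of the 19 had a negative difference. Cholesterol synthesis genes were higher (2 of 20 up, 4 up and 1 down adjusted over the list alone; mean 0.19, camera adjusted p = 0.000904, adjusted p = 0.685 with an estimated correlation). Collagens and extracellular matrix were lower with the antibody by −0.81 on average, with 1 of 25 down, Thbs1, and 4 adjusted over the list alone (camera adjusted p = 7.7e-11). Proliferation genes were lower (−0.50, camera adjusted p = 0.000138), with 0 of 20 passing and 0 at an unadjusted p under 0.05 in limma. Fibroblast and adipose progenitor markers were lower too (−0.43, camera adjusted p = 0.0021), with 0 of 12 passing in limma and 1 at an unadjusted p under 0.05. With an estimated correlation each of these 3 lists had an adjusted p of 0.685. Macrophage markers moved with them (−0.63, 0 of 22 passing and 0 at an unadjusted p under 0.05 in limma; camera adjusted p = 0.000686, adjusted p = 0.685 with an estimated correlation), and differed by −0.30 without FGF21 36 (adjusted p = 0.135).

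7 further lists passed in camera, each with an adjusted p of 0.685 with an estimated correlation and with 0 members passing singly in limma. Oxidative phosphorylation (0.07, adjusted p = 0.000517, 1 of 69 members at an unadjusted p under 0.05), fatty acid oxidation (0.15, adjusted p = 0.0021, 3 of 23), branched-chain amino acid catabolism (0.16, adjusted p = 0.0021, 1 of 21) and thermogenic genes (0.11, adjusted p = 0.0183, 9 of 28) were higher with the antibody. Ribosomal protein genes (−0.08, adjusted p = 0.00816, 1 of 27), immediate early genes (−0.26, adjusted p = 0.0129, 5 of 14) and inflammatory cytokines and chemokines (−0.33, adjusted p = 0.0191, 2 of 20) were lower. Without FGF21 36 all 7 missed the threshold, with adjusted p of 0.183, 0.135, 0.189, 0.482, 0.356, 0.0509 and 0.135 in that order, and ribosomal protein genes also did without FGF21 39 (adjusted p = 0.061). Without control 34 and FGF21 36 together, immediate early genes passed (−0.19, adjusted p = 0.0457, but 0.749 in camera with an estimated correlation) and the other 6 did not.

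**Figure D2:**
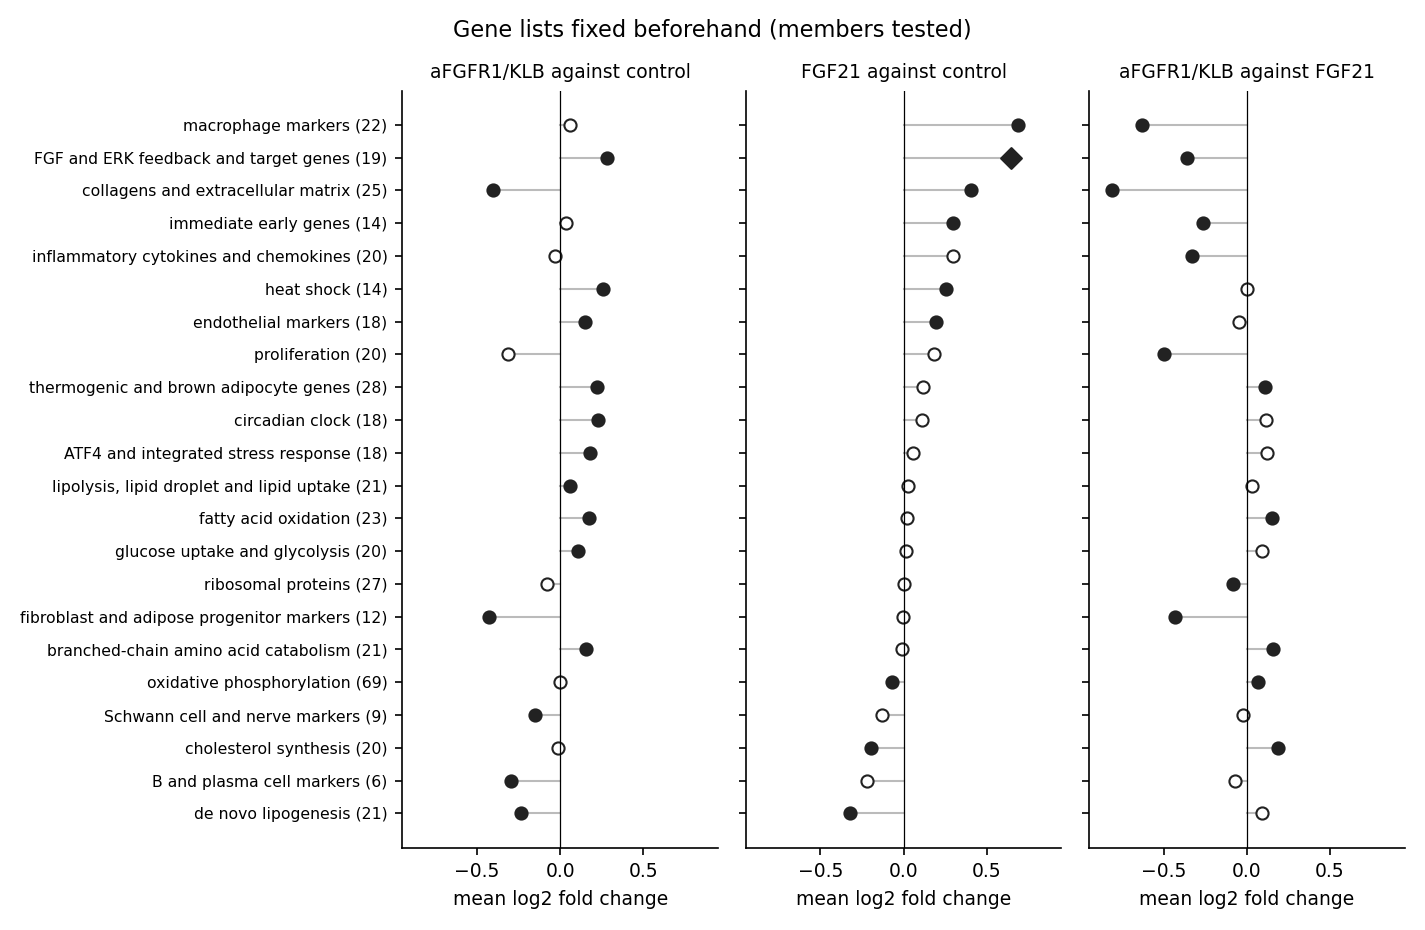
Mean log2 fold change of the members of each gene list that passed in at least 1 comparison, with the number of members tested in brackets. Filled symbols passed in camera with the preset correlation and the diamond, FGF and ERK feedback genes with FGF21, passed with an estimated correlation too; open symbols did not pass.

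Whether both treatments change the same transcripts was asked across genes. Fold changes against control correlated at r = 0.595 over the 13174 genes (SE 0.219 from leaving out each sample in turn; genes are not independent replicates). 154 genes rose and 186 fell with both, where independent lists of these sizes would share 9.35 and 12.1. 0 genes changed in opposite directions in limma, where independent lists give 13 and 8.66; among the 1175 genes called with either treatment, 39 had fold changes of opposite sign. Both comparisons use the same 5 controls, so calls can agree without a shared response, and independent lists do not allow for that. With the controls divided between both comparisons in 20 ways, limma called 20 to 58 genes up and 5 to 70 down with both, where independent lists give at most 4.12 and 4.02. It called 0 or 1 in opposite directions, where independent lists give 0.548 to 9.59. Unchanged groups were simulated from the residuals of all 15 samples, with 1 simulated control group for both comparisons. They gave a mean r of 0.439 with 95% of values between −0.544 and 0.952. The covariance of the fold changes was 0.0341 against 0.0187 in that simulation, whose upper limit was 0.0853. With the controls divided between both comparisons, r had a median of 0.346 over 20 divisions (−0.224 to 0.659). Pla2g2e, Ak4, Ffar4, Itih4, Sgk2 and Kit were among the genes that changed with both at similar size, with differences between treatments of −0.08, 0.15, 0.29, 0.11, 0.42 and 0.13, none of which passed.

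**Figure D3:**
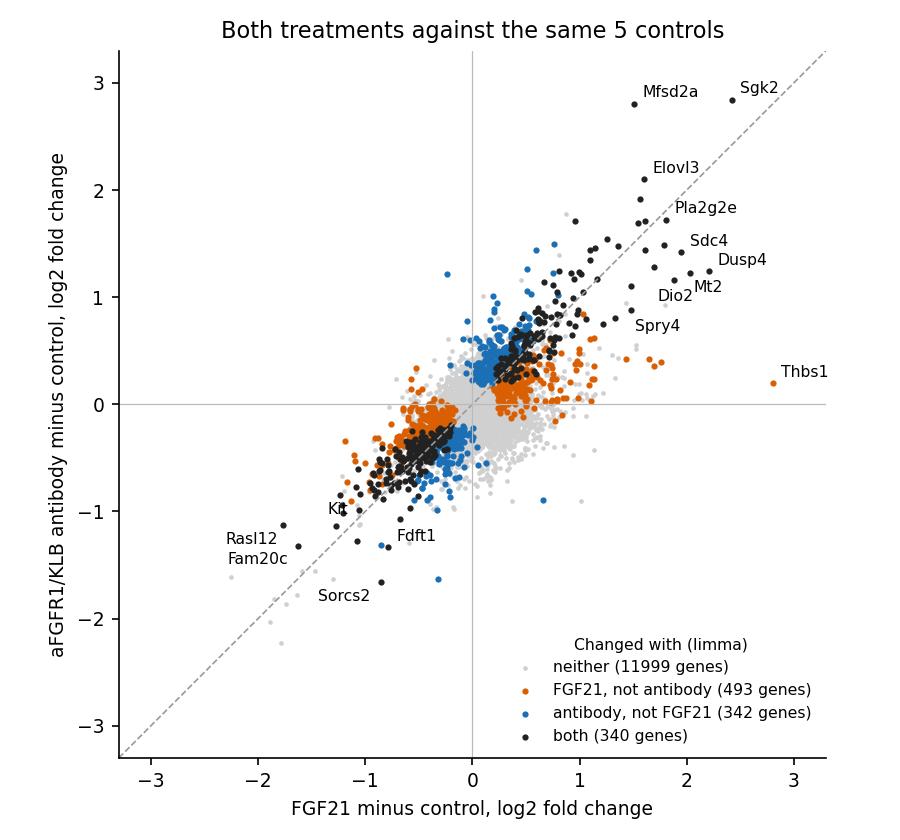
Log2 fold change of each of 13174 genes with the antibody (vertical) against FGF21 (horizontal), coloured by whether limma called the gene with both treatments (340 genes), with either or with neither. The dashed line marks equal change; Thbs1 lies far to its right, and Mfsd2a above it.

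Fgfr1, Klb and Fgf21 did not pass in limma with either treatment. Fgfr1 differed from control by −0.08 with the antibody (adjusted p = 0.770) and −0.07 with FGF21 (adjusted p = 0.796), and Klb by −0.22 (adjusted p = 0.321) and −0.40 (adjusted p = 0.0529). All 5 Klb values with FGF21 lay below all 5 control values, and Klb passed without control 34 (−0.45, adjusted p = 0.023), FGF21 39 (−0.46, adjusted p = 0.0484) or aFGFR1/KLB 45 (adjusted p = 0.048). Endogenous Fgf21 was 0.61 ± 0.22 above control with the antibody (adjusted p = 0.128) and 0.05 ± 0.22 with FGF21 (adjusted p = 0.933). With macrophage and muscle means as covariates, Fgf21 passed with the antibody (0.56, adjusted p = 0.048). Adipoq, the adiponectin gene of fat cells, differed by 0.03 (adjusted p = 0.796) and 0.05 (adjusted p = 0.641).

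Samples also differed in transcripts of other tissues and cells. Skeletal muscle markers ranged from −3.35 (FGF21 38) to 3.93 (aFGFR1/KLB 45) around the mean of all samples, with FGF21 36 second highest at 3.76, and Myh1, a myosin heavy chain of fast muscle fibres, spanned 1847-fold. The muscle list did not pass with the antibody (mean −0.68, camera adjusted p = 0.646; 0 of 26 members in limma, 1 at an unadjusted p under 0.05) or with FGF21 (mean −0.74, camera adjusted p = 0.646; 0 of 26 in limma, 0 at an unadjusted p under 0.05). It passed with the antibody without aFGFR1/KLB 45 (−1.71, adjusted p = 0.0084) or centred on ribosomal protein genes (−0.55, adjusted p = 0.00131), and with FGF21 without FGF21 36 (−1.75, adjusted p = 0.0282). Macrophage markers stood at 1.52 in control 34 and 1.76 in FGF21 36, collagens at 1.35 and 1.34 and proliferation genes at 1.33 and 0.96. Without both samples, 1631 genes changed with the antibody and 2138 with FGF21, including 676 of the 682 and 808 of the 833 genes above. Macrophage markers averaged 0.06 with the antibody (camera adjusted p = 0.824) and passed without both samples (0.50, adjusted p = 0.00951). Unfolded protein response genes did not pass with all samples but passed without both, with the antibody (0.14, adjusted p = 0.00186) and with FGF21 (0.15, adjusted p = 0.00454). So did cytokines and chemokines (0.44, adjusted p = 0.0054) and proliferation genes (0.32, adjusted p = 0.00734) with FGF21, but with a macrophage covariate proliferation genes passed in the opposite direction (−0.26, adjusted p = 0.00107). With an estimated correlation the 5 calls without both samples had adjusted p between 0.348 and 0.813.

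**Figure D4:**
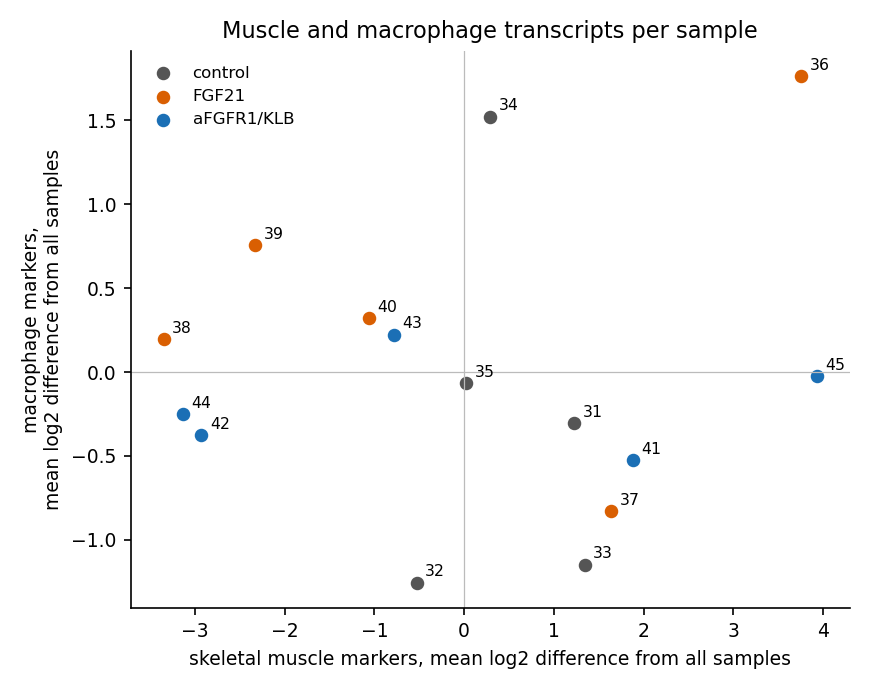
Mean of the skeletal muscle markers (horizontal) and of the macrophage markers (vertical) in each sample, as log2 differences from the mean of all samples; numbers are the replicate numbers. Control 34 and FGF21 36 lie highest in macrophage markers, at 1.52 and 1.76.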

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

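All tests of this part were chosen after the results were seen, except the splits of the samples, the first test for a wrong label and the test of the muscle markers as 1 source.

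33 of 273 groups of 5 values (12.1%; 108 of list means and 165 of named genes) held a sample far from the other 4, where chance gives about 1 in 20 groups, and the tests share samples and genes. Differences below are log2 differences from the median of the other 4 samples of the group. 17 of the 33 lay in control 34. Its list means were higher for interferon-stimulated genes (1.77), collagens and extracellular matrix (1.74), proliferation (1.60), inflammatory cytokines and chemokines (1.30), immediate early genes (0.563), ribosomal proteins (0.414), endoplasmic reticulum chaperones and unfolded protein response (0.378) and neutrophil markers (0.360). They were lower for branched-chain amino acid catabolism (−0.380), glycerolipid synthesis (−0.305), the TCA cycle (−0.279), the circadian clock (−0.244) and lipolysis (−0.207). Among its genes, Net1 (0.687) was higher and Pnpla3 (−1.01), Rasd1 (−0.892) and Elovl3 (−0.868) were lower.

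FGF21 36 differed from its group in branched-chain amino acid catabolism (−0.509), the TCA cycle (−0.371), oxidative phosphorylation (−0.207), the circadian clock (−0.156), Hmga2-ps1 (0.905), Dusp4 (−0.524) and Ucp1 (−0.174). FGF21 38 differed in Fgf21 (0.900) and the list of FGF receptors, co-receptors and ligands (0.125). aFGFR1/KLB 45 differed in Sgk2 (−1.15), S100g (−0.549), Sorcs2 (0.372) and fatty acid oxidation (−0.115), and aFGFR1/KLB 41 in Net1 (0.550), Ntrk3 (−0.528) and Schwann cell and nerve markers (0.127).

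The first pattern weighed is the high macrophage list of control 34 (1.52) and FGF21 36 (1.76), where Gpnmb stood 4.14 and 3.11, Lyz2 2.33 and 1.56 and C1qb 2.20 and 1.87 above the other 4 samples of the group; 21 of the 22 markers were above the intensity filter in the sample with the lowest score too, and 0 are in another list. For array quality, 10000 random lists matched on mean level reached at most 0.418 and 0.574 (percentile 100 in both samples). These lists were drawn from unrelated genes. Markers that move together, chosen for their height in these samples, would exceed them in any case, so array quality stays open. Muscle in control 34 is argued against by a muscle mean 1.06 under the highest other control (SD 0.92). In FGF21 36, with a muscle mean of 3.76, muscle is argued against by its macrophage markers. They stood 2.40 above the value that a line of macrophage on muscle mean through the other 13 samples gives (residual SD 0.57). Against lymph node tissue stand 14 T and B cell markers, whose larger median difference was −0.0166 (median absolute deviation 0.20). A first version of this test, replaced after it was seen, had Ighm 0.90 below the highest other sample. However, Il7r stood 2.99 and 2.73 and Thy1 1.68 and 1.00 higher, and Ighm 0.80 higher in FGF21 36. The T cell gene Cd3e did not rise (0.008 in control 34 and −0.03 in FGF21 36), and Ighm was lower in control 34 (−0.525). The T cell list mean was 0.41 in control 34 and 0.43 in FGF21 36, against at most 0.30 in any other sample. The B and plasma cell list mean of control 34 (0.17) lay within the range of the other controls (0.11 to 0.29). That of FGF21 36 (0.13) lay above its group (at most 0.05), so lymph node tissue is not excluded. For a wrong label of control 34, the test set beforehand took the 795 genes that both treatments changed without it. The median position of control 34 between the other controls (0) and the treated samples (1) was 0.48 over the 292 genes higher with both treatments and 0.84 over the 503 lower with both. Over all 795 genes it was 0.76 (SD of treated samples 0.07), against a limit of 0.75, so the test came out in favour. Every treated sample lay higher, between 0.89 and 1.12. A second test, chosen after that value was seen and resting on the most changed genes alone, came out against (0.22 over 54 genes changed at least 2-fold, SD 0.12), control 34 lay with the controls in the third principal component (18.1; controls 11.9 to 18.2, treated −13.3 to −4.38), and it stood below every treated sample in Dio2 (9.08, lowest treated 9.81), Dusp6 (9.65, 10.43) and Spry4 (6.93, 7.57), named before the data, but not in Ppargc1a (10.19, 10.13; largest position of the 4 genes 0.16, where the largest SD of treated samples was 0.53), while its FGF and ERK list mean (0.05) lay above the other controls (at most −0.30) and all antibody samples (at most 0.01); of the genes where the other controls and the treated samples did not overlap, control 34 lay on the control side for 29 of 46 changed at least 2-fold and within the treated range or beyond for 433 of all 663, so the values go both ways and a wrong label stays open, as do a local inflammation or other tissue in both pieces, and no biological explanation was tested.

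The second pattern is the spread of skeletal muscle markers from −3.35 to 3.93. The 26 markers moved as 1 source, with 93.4% of their variance in the first principal component, which is consistent with muscle carried along in dissection; 12 of the 26 were above the intensity filter in the sample with the lowest score, and 0 are in another list. The most variable were Myh1 (1847-fold) and Acta1 (904-fold). Whether treatment added to the spread cannot be told apart from it: the smaller exact p of the list mean was 0.595, and the differences from control were −0.68 (SE 1.42) with the antibody and −0.74 (SE 1.35) with FGF21.

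The third pattern is the lower FGF and ERK feedback list with the antibody than with FGF21 (−0.36, SE 0.08, with 16 of 19 members lower). Tissue differences are argued against as its whole cause. The difference was −0.35 (SE 0.04) without control 34 and FGF21 36, −0.28 (SE 0.05) with the macrophage mean as a covariate and −0.36 (SE 0.09) with the muscle mean as a covariate. Dose, schedule and the nature of the ligand differ together between these groups, so they stay open, and the difference may reflect any of them.

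For the antibody against control, 1 of 100 splits of the 10 samples, the real one, gave as many as 682 genes (highest other 14), which argues against chance. Between the treatments 1 of 100 gave as many as 49, but the highest other split gave 45, so chance is not excluded there. For FGF21 against control 3 of 100 splits gave at least 833 genes, so this count alone does not exclude chance. The other 2 gave 1413 and 2498 genes, and both put control 34 on the side of the FGF21 samples in exchange for FGF21 38 or FGF21 37, which points to a structure of the samples around control 34.

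Of 4194 probe sets tested that carry several symbols or are unnamed here, 88 changed with the antibody (52 up, 36 down), 110 with FGF21 (72 up, 38 down) and 15 between the treatments (1 up, 14 down) by limma. The largest changes were 2.11 and −2.48 with the antibody, 4.18 and −1.75 with FGF21 and 0.84 and −3.52 between the treatments, each on a probe set unnamed here except 4.18 and −3.52, whose shared probe set carries several symbols.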

How the results depend on the processing

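The alternatives without control 34 and FGF21 36 and with macrophage covariates were chosen after the results were seen. Signal limits this part through the intensity filter: at the 60th percentile 77 genes differed between the treatments. Numbers below are genes changed with the antibody, with FGF21 and between the treatments, beside 682, 833 and 49; unless stated, the cause was not tested.

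Every probe set tested on its own gave 1184, 1358 and 103 probe sets, since several count for 1 gene. Centring on ribosomal protein genes gave 134, 137 and 8, array weights 2307, 2855 and 832. Only the 2 groups compared gave 322 with FGF21 and 87 between the treatments. A trend gave 76, a robust trend 81 and a muscle covariate 95 between the treatments. An adjusted p under 0.01 gave 171, 275 and 10, and a fold of at least 1.5 gave 214, 237 and 18, stricter by construction. Without control 34 and FGF21 36 the counts were 1631, 2138 and 241, with a macrophage covariate 1799, 1333 and 127, and with macrophage and muscle covariates 2059, 1423 and 223. Leaving out 1 sample gave 336 to 1140, 463 to 2097 and 10 to 251, the highest without control 34 each time and the lowest without aFGFR1/KLB 42, control 32 and FGF21 40. The correlation between the treatments was 0.469 to 0.716 over the latter and 0.759 without both samples.

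With a macrophage covariate these list means for FGF21 against control turned and passed in the new direction: branched-chain amino acids 0.11 (adjusted p = 0.0335), interferon-stimulated genes −0.35 (0.00841), proliferation −0.26 (0.00107) and ribosomal proteins −0.11 (0.000647). Collagens turned to −0.0528 (0.418) and ribosomal proteins between the treatments to 0.0182 (0.584), which did not pass. With both covariates they were −0.35 (interferon, 0.0146), −0.27 (proliferation, 0.00105) and −0.11 (ribosomal proteins, FGF21, 0.000965), which passed, and −0.0337 (collagens, 0.638) and 0.0192 (ribosomal proteins, between the treatments, 0.621), which did not. Skeletal muscle between the treatments (0.06) was −0.97 without aFGFR1/KLB 45 and 1.07 without FGF21 36, the lowest and highest values. A list has no value where it is itself the covariate or reference.

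Of the named gene calls, 26 of 50 with the antibody, 25 of 38 with FGF21 and 4 of 17 between the treatments held in every alternative that tested them. Of the list calls it was 0 of 15, 1 of 9 (FGF and ERK feedback) and 0 of 13, and on leaving out 1 sample 4, 5 and 5. Centring on ribosomal proteins ended 44 of 105 named gene calls.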

Other observations

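The tests of this part were set before their results were seen, although the name of the lipogenesis explanation was reworded afterwards with its limits kept. A candidate explanation for the rise of clock genes is a different time of tissue collection. A phase difference moves genes of opposite phase apart, but the Dbp and Per group averaged 0.32 (SE 0.10) with the antibody and 0.21 (SE 0.10) with FGF21, and the Arntl and Clock group 0.37 (SE 0.07) and 0.22 (SE 0.09), so both rose and the smaller Dbp and Per mean was 0.21. These values go against a shift that moves the 2 groups apart as the whole cause. The Arntl and Clock group held only 4 tested genes, and a shift that raises both groups was not tested. The whole clock list stood at −0.31 in control 34, against −0.09 to −0.03 in the other controls, and the group means were not computed without that sample. A different time of collection therefore stays open. Times of collection are not given in the labels.

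A hypothesis for the lower lipogenesis list is that the same members fall with both treatments. With different controls serving each treatment, the fold changes of its 21 members correlated with a median r of 0.645 over 20 splits (0.304 to 0.821), which goes with the hypothesis.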
